A study of Mus musculus with 12 samples.

How the data were processed

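Gene expression was measured by RNA sequencing in mouse bone cells sorted for F4/80, the macrophage surface protein encoded by Adgre1. The labels call these cells osteal macrophages, the resident macrophages of bone surfaces. Per the labels' protocols, bone was digested with trypsin and then overnight with collagenase D before the sort. Directional libraries were made with a NEBNext Ultra II kit and sequenced in pairs on a NovaSeq instrument. The 12 libraries form 4 groups of 3. These are untreated controls, mice given 3% dextran sulfate sodium (DSS) in drinking water for 5 days with cells taken after 1 week, and the same treatment with cells taken after 3 weeks. The remaining group holds mice injected with 5 mg/kg lipopolysaccharide (LPS) with cells taken after 3 days. DSS injures the lining of the colon and is used to produce colitis. LPS is a component of bacterial outer membranes that activates Toll-like receptor 4.

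The deposited table holds raw counts per gene, and the values were whole numbers whose totals differ between libraries. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 to the GRCm39 mouse genome and counted with featureCounts 1.55.0-p3. The strand setting of the counting, the handling of reads that match several places and any gene filter are not given in the sources used here. Reads of overlapping, antisense or near-identical genes can therefore not be assigned with certainty. This concerns the stefin genes (Stfa and Cstdc symbols), the Ifit3 and Ifit3b pair, the Ifi200 genes (such as Ifi205, Ifi206, Ifi208 and Ifi211), the Ear genes and the alpha globin genes. Gene names, identifiers and GRCm39 coordinates were taken from the deposited table, as was gene length, which entered no test. The table listed 46333 genes, and 3 symbols stood for more than 1 gene. Levels are given as CPM, a gene's count relative to its library's total. Totals ranged from 15428396 to 22576892 counts per library, so genes with a mean under about 1 CPM rest on few counts.

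Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by edgeR's filter on group size with a minimum count of 10 and a minimum total of 15, which left 14516 genes. Libraries were scaled by trimmed mean of M values, and CPM values carry that scaling. All 12 libraries entered 1 quasi-likelihood fit with robust dispersion and group as the only factor, so that the groups share an estimate of spread. Each comparison was a contrast in that fit, two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05, the false discovery rate given in the labels. There were 4 main comparisons: each treated group with control, and 3 weeks with 1 week after DSS. The other contrasts set each DSS group against LPS. These equal the difference between the responses to the treatments against the common control. Fold changes are fitted log2 values with standard errors (SE), and levels are CPM means with standard deviations (SD) over 3 libraries. Unless another tool is named, adjusted p-values of genes come from edgeR's quasi-likelihood test.

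The pipeline was tested on simulated data with the means and library sizes of the real libraries and 200 genes changed. For 3 weeks of DSS against control it recovered 42.3% of genes changed by 1 log2 unit and 73% of those changed by 2, with 8 false calls among 14324 genes. For 1 week of DSS these shares were 35.7% and 70.7% with 3 false calls among 14308 genes. For LPS they were 37.6% and 67.7% with 9 among 14330. For 3 weeks against 1 week they were 41.8% and 74.7% with 5 among 14355. The simulated libraries had the same spread per gene in all groups and no effect of library naming. The real groups differ in spread, as described below, so these shares and false calls do not show the error rate in the real libraries.

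Gene lists were written before the data were examined, as were the tests, the rule for named genes and most alternatives. There were 28 lists, of which 14 hold markers of cell types other than macrophages that the sort could contain. Each list was tested in each comparison with limma's camera on edgeR's z scores, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. The same test was run with an estimated correlation, and limma's fry test was run as another alternative. Members past the threshold are counted over all genes tested and also adjusted over the list alone. Some lists share genes: Bst2 stands in the interferon and dendritic cell lists, Vegfa in the glycolysis and bone factor lists, and Il1b, Il6 and Osm in the inflammatory and bone factor lists.

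Named genes were chosen by a rule. For each main comparison these were up to 8 genes with the largest rise and 8 with the largest fall among those past the threshold, with no overlap between the libraries of both groups and a mean of at least 5 CPM in the higher group. Predicted genes, pseudogenes, ribosomal protein genes and antigen receptor segments were left out. Up to 4 members with the smallest p-value were added from each list described, and 10 genes of bone and macrophage biology (Adgre1, Csf1r, Tnf, Il1b, Il6, Nos2, Tnfsf11, Osm, Igf1 and Arg1) were given for each comparison with control. Where fewer than 16 genes passed, those with the smallest p-values that did not pass were given up to a total of 10.

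Library names in the labels fall into a numbered and a lettered series. All libraries from 3 weeks after DSS are numbered, while the control and 1-week groups each hold 1 numbered and 2 lettered libraries and the LPS group holds 2 numbered and 1 lettered. The 3-week names are also written in a format that the other numbered names do not share. What the naming stands for is not stated. If that format marks a separate batch, this batch coincides with the 3-week group. Neither the name series as a covariate nor the numbered libraries alone could then correct for it. With the group as a second factor, 250 genes differed between numbered and lettered libraries (129 higher and 121 lower in the numbered ones), with 2498 at an unadjusted p under 0.05. Deviations from the group means had a median correlation of 0.08 over 25 pairs of libraries in the same series, with 10 pairs over 0.1, and of -0.03 over 29 pairs in different series, with 0 over 0.1. List medians among the numbered or the lettered libraries alone are therefore given for comparisons against control and between 3 weeks and 1 week. Between numbered libraries the control and 1-week groups hold 1 library each, so such values have no replication in those groups.

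Alternatives covered other scalings, other filters on low counts, DESeq2 1.42.0, limma voom with and without sample weights, and fits to only the groups compared. They also covered blocks by replicate number or by the last character of the library name, the name series as a covariate, protein-coding genes only, leaving out the 50 most abundant genes, and leaving out each library in turn. After the data were examined, 3 further settings were added: leaving out control replicate 2 and LPS replicate 2 together, summing the 3-week DSS libraries to 1, and using only numbered libraries in 1 fit over the 4 groups.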

Results

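Osteal macrophages were profiled in 12 mouse libraries, 3 from untreated controls, 3 taken 1 week after DSS, 3 taken 3 weeks after DSS and 3 taken 3 days after LPS. The series title names chronic colitis, osteoporosis and the inflammatory state of these cells, and the comparisons ask how their transcripts differ from controls after gut injury and after systemic LPS. Total counts ran from 15428396 to 22576892 per library. Adgre1, which encodes F4/80, was detected in every library at 288 to 774 CPM. Csf1r, the receptor for the macrophage growth factor CSF1, lay at 687 to 2050 CPM. The macrophage core list had a mean log2 CPM of 8.58 ± 0.36 in controls, 8.98 ± 0.08 at 1 week, 8.23 ± 0.02 at 3 weeks and 8.59 ± 0.69 after LPS (SD, n = 3 each). The neutrophil and granulocyte precursor list was also detected, at 5.99 ± 0.51 in controls. Its member S100a9 stood at 577.06, 788.3 and 1069.39 CPM in control replicates 1, 2 and 3, against 497, 288 and 442 for Adgre1. Ly6g of the same list stood at 2.59 to 3.58 CPM. The libraries may therefore hold RNA of cells other than macrophages. The labels do not state whether libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

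Libraries of the same group differed in their own ways. Control replicate 2 stood apart on the first principal component at 106.7, against -42.2 to 21.5 for the other libraries, and had a proliferation list level of 6.42 log2 CPM against 4.03 and 5.39 in the other controls. LPS replicate 2 stood apart on the third component at 69.5, with S100a8 at 4444.7 CPM against 926.91 and 1600.86 in the other LPS libraries. The libraries from 3 weeks after DSS were close to each other. With counting noise left out, their median coefficient of variation per gene was 0.028. It was 0.158 in controls, 0.08 at 1 week and 0.124 after LPS. Chi-square over degrees of freedom was 3.9, 4.7 and 7 for pairs of 3-week libraries, and 7.9 for replicates 2 and 3 from 1 week. The 3-week group was analysed as 3 libraries, as listed in the labels. Mitochondrial genes took 1.31% to 1.42% of counts in the LPS libraries and 0.78% to 1.09% in the others. Across all groups, 1076 of 14516 genes changed in an F test of the 3 treatment terms. This count ran from 47 (without 3-week replicate 1) to 2593 (without control replicate 1) on leaving out a library, and was 13 with a block by name suffix and 3 with the 3-week libraries summed.

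**Figure D1:**
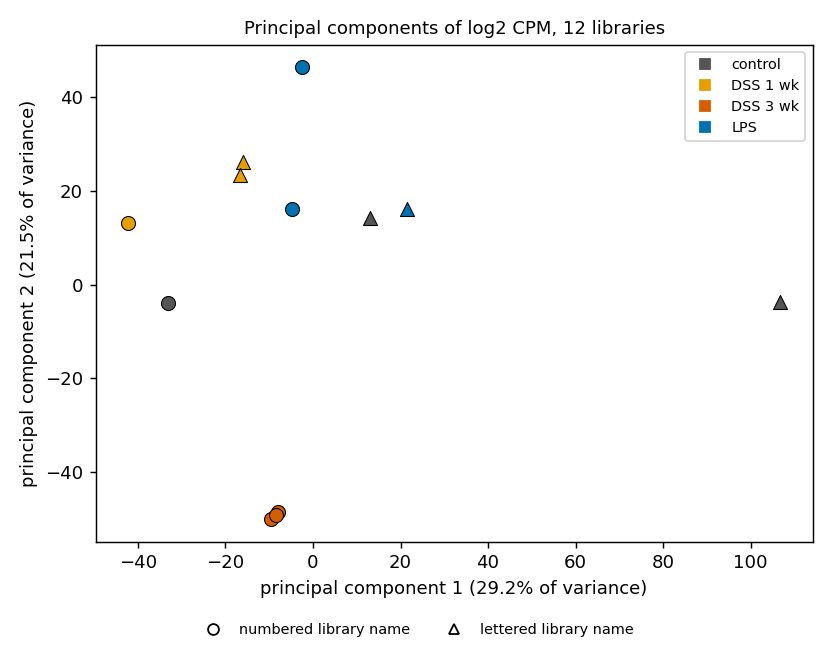
Each point is a library placed by its first and second principal component of log2 CPM, which hold 29.2% and 21.5% of the variance, with circles for numbered and triangles for lettered library names. Control replicate 2 lies at 106.7 on the first component, and the 3-week DSS libraries lie together between -50 and -48.5 on the second.

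At 1 week after DSS, Cstdc5 and Stfa2, which encode stefin A inhibitors of cysteine proteases, rose and were the only genes past the threshold. Lists of neutrophil genes, with higher values, and of bone-forming cell and eosinophil genes, with lower ones, passed with a preset correlation but not with an estimated one (adjusted p = 0.209, 0.486 and 0.625 with an estimated correlation). Cstdc5 (gene 100034684, chromosome 16, 36179744 to 36187932) rose 33.3-fold, from 0.26 ± 0.145 to 8.62 ± 0.349 CPM (SD, n = 3 each; log2 fold change 5.06, SE 0.51, adjusted p = 0.0112). Stfa2 (gene 20862, chromosome 16, 36224308 to 36228725) rose 23-fold, from 0.361 ± 0.127 to 8.37 ± 0.989 CPM (log2 fold change 4.52, SE 0.49, adjusted p = 0.0116). Both rest on a few counts per control library and on genes that share sequence with close copies. The acute-phase gene Saa3 stood at 648 ± 67.1 CPM against 27.1 ± 21.1 in controls, a 23.9-fold difference with an adjusted p of 0.0634.

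Further genes with an adjusted p of 0.0634 were above every control in all 3 libraries. They included the stefins Stfa2l1 (26.1 ± 9.57 against 4.2 ± 2 CPM), Cstdc4 (26.7 ± 8.98 against 4.1 ± 2.1) and Stfa1 (5.39 ± 0.998 against 0.316 ± 0.251), and the protease gene Asprv1 (104 ± 14.7 against 19.7 ± 5.28). Ptgr1, which inactivates prostaglandins and leukotriene B4, stood at 192 ± 8.28 against 93.3 ± 12.3 CPM, Ggt5, which converts leukotriene C4 to D4, at 20 ± 3.61 against 7.5 ± 1.58, and Abtb1 at 73.8 ± 4.36 against 40.4 ± 4.55. In the neutrophil and granulocyte precursor list, 1 of 19 measured members rose over all genes and 7 did when adjusted over the list alone, with a median log2 fold change of 0.75 (camera adjusted p = 2e-15; adjusted p = 0.209 with an estimated correlation). The member that rose was Stfa2. Ly6g, the neutrophil surface antigen, had a log2 fold change of 2.23 (SE 0.35, adjusted p = 0.0645) and Lcn2, the iron-trapping lipocalin 2, of 1.56 (SE 0.32, adjusted p = 0.206).

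Macrophage and innate signalling lists had higher values by smaller amounts at 1 week, though not between the numbered libraries, which are 1 control and 1 DSS library. In each of these lists edgeR called 0 members, while 2209 of all genes had an unadjusted p under 0.05 and DESeq2 called 240 genes and limma voom 0. The macrophage core list, 20 of whose 22 members were positive, had a median log2 fold change of 0.35 (camera adjusted p = 1.21e-05). NF-kB feedback genes, which NF-kB induces and which restrain or transmit its activity, had a median of 0.49 (adjusted p = 9.02e-06). All 26 Toll-like receptor and inflammasome genes were positive with a median of 0.27 (adjusted p = 1.06e-05). For each of these 3 lists the adjusted p was 0.625 with an estimated correlation, and the median was -0.02 between the numbered libraries. Examples are Adgre1 at 727 ± 55.1 against 409 ± 108 CPM (adjusted p = 0.297) and the lysozyme gene Lyz2 with a log2 fold change of 0.90 (SE 0.28, adjusted p = 0.297). Others are the NF-kB cofactor gene Bcl3 with 0.54 (SE 0.16, adjusted p = 0.297) and Irak3, which dampens Toll-like receptor signals, with 0.75 (SE 0.31, adjusted p = 0.311). The monocyte list had a median of 0.19 (adjusted p = 0.0395; adjusted p = 0.625 with an estimated correlation), led by the haptoglobin gene Hp at 1.35 (SE 0.38, adjusted p = 0.297). Its median was 0.04 between numbered and 0.50 among lettered libraries, and those of neutrophil genes were 1.58 and 0.49.

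The osteoblast, eosinophil and proliferation lists were lower at 1 week. The osteoblast and osteocyte list had a median log2 fold change of -2.32 over 9 measured members, of which 0 fell over all genes and 5 did when adjusted over the list alone (camera adjusted p = 0.000293; adjusted p = 0.486 with an estimated correlation). Collagen I transcripts stood at 3.19 against 16 CPM for Col1a1 (adjusted p = 0.194) and 0.592 against 11.5 CPM for Col1a2 (adjusted p = 0.207). Alpl, the bone mineralization phosphatase, stood at 0.393 against 11 CPM (adjusted p = 0.297) and the osteocyte matrix gene Dmp1 at 0.0633 against 3.26 CPM (adjusted p = 0.297). All 10 eosinophil markers were negative, with a median of -1.21 (adjusted p = 0.000293; adjusted p = 0.625 with an estimated correlation), among them the lipoxygenase gene Alox15 at -1.56 (SE 0.59, adjusted p = 0.303) and the ribonuclease gene Ear2 at -0.90 (SE 0.41, adjusted p = 0.329). Between numbered and among lettered libraries the osteoblast medians were -2.77 and -1.81, and the eosinophil medians -0.87 and -1.31. All 26 proliferation genes were negative (adjusted p = 1.37e-05; adjusted p = 0.874 with an estimated correlation). Their median was -1.46 among the lettered libraries, 0.61 between the numbered ones and -0.26 (adjusted p = 0.116) without control replicate 2 and LPS replicate 2.

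Cytokine and bone-acting genes fixed beforehand did not pass at 1 week. Tnf stood at 56.8 ± 8.3 against 38.3 ± 9.32 CPM (adjusted p = 0.69), and Il1b at 167 ± 104 against 92 ± 40.9 (adjusted p = 0.576). Il6 stood at 5.08 ± 1.4 against 8.01 ± 2.15 (adjusted p = 0.423) and the nitric oxide synthase gene Nos2 at 182 ± 168 against 61.6 ± 75.2 (adjusted p = 0.42). Csf1r stood at 1720 ± 229 against 1120 ± 468 CPM (adjusted p = 0.321) and Osm, a cytokine that acts on osteoblasts, at 77.7 ± 21.8 against 95.9 ± 27.9 (adjusted p = 0.55). Igf1 stood at 71.3 ± 22.2 against 49.1 ± 16.4 (adjusted p = 0.6) and Arg1 at 789 ± 71.5 against 611 ± 205 (adjusted p = 0.856). Tnfsf11, which encodes the osteoclast-inducing ligand RANKL, had 0 to 7 counts per library over the 12 libraries and was not tested. The inflammatory mediator list had a median of 0.18 (camera adjusted p = 0.0113; adjusted p = 0.625 with an estimated correlation) with Saa3 as its only member past the threshold when adjusted over the list alone. That median was 0.51 among the lettered libraries and -0.28 between the numbered ones. Interferon response genes had a median of 0.21 (adjusted p = 0.213), with 0.49 among lettered and -0.86 between numbered libraries.

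In all, 2 genes changed at 1 week, both higher, and 16.6% of genes had no overlap between the groups, against 10% by chance. DESeq2 called 240 genes, limma voom 0 (1587 at an unadjusted p under 0.05) and voom with sample weights 824. The lettered libraries alone gave 1 gene, which was neither Cstdc5 nor Stfa2. Without DSS replicate 3 the count was 0, with 1321 genes at an unadjusted p under 0.05.

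At 3 weeks after DSS, the prostaglandin E2 genes Ptgs2 and Ptges, some NF-kB target genes and a few glycolysis and hypoxia genes rose. Many interferon-induced genes fell against the same controls. The lists of NF-kB, glycolysis and interferon genes passed with a preset correlation but not with an estimated one (adjusted p = 0.255, 0.351 and 0.255 with an estimated correlation). Ptgs2 (gene 19225, chromosome 1, 149975782 to 149983985), which encodes cyclooxygenase 2, rose 6.64-fold, from 90.7 ± 12.6 to 602 ± 15.7 CPM (SD, n = 3 each; log2 fold change 2.73, SE 0.22, adjusted p = 0.000427). Ptges (gene 64292, chromosome 2, 30779483 to 30793309), the inducible prostaglandin E synthase, rose 7.48-fold, from 14.3 ± 9.77 to 107 ± 4.14 CPM (log2 fold change 2.90, SE 0.49, adjusted p = 0.0166). The interferon-induced gene Ifit3 (gene 15959, chromosome 19, 34560519 to 34566382) was 22.9-fold lower, at 6.16 ± 0.357 against 141 ± 45.9 CPM (log2 fold change -4.51, SE 0.85, adjusted p = 0.0233). Siglec1 (gene 20612, chromosome 2, 130911140 to 130928697), the CD169 lectin of resident macrophages, was 10.5-fold lower, at 30.4 ± 1.35 against 320 ± 79.2 CPM (log2 fold change -3.40, SE 0.59, adjusted p = 0.0176).

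Other large rises at 3 weeks were Htr7, a serotonin receptor gene (7.49-fold, adjusted p = 0.0219), Tnfrsf9, the costimulatory receptor 4-1BB (6.7-fold, adjusted p = 0.0193), and the androglobin gene Adgb (6.15-fold, adjusted p = 0.0156). Others were Ccr3, the eotaxin receptor of eosinophils (5.85-fold, adjusted p = 0.0144), Txlnb (5.55-fold, adjusted p = 0.0112) and Fosl1, the AP-1 subunit Fra-1 (5.13-fold, adjusted p = 0.00691). Other large falls were Ifit3b (27.5-fold lower, adjusted p = 0.0278), Ifi44 (16.2-fold lower, adjusted p = 0.0278), Ifit2 (13.9-fold lower, adjusted p = 0.0251) and Ifi206 (10.2-fold lower, adjusted p = 0.0456), all induced by interferon. The extracellular matrix gene Spon1 fell too, to 0.142 ± 0.0902 from 7.2 ± 4.83 CPM (adjusted p = 0.0396). The transcription factor gene Pou3f1 fell from 6.16 ± 8.81 to 0.0528 ± 0.0915 CPM (adjusted p = 0.0486). The control mean was set by 16.28 CPM in control replicate 2 against 0.24 and 1.97 in the others.

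All 29 measured interferon response genes were lower at 3 weeks, with a median log2 fold change of -1.85. Of these, 17 fell over all genes and 27 did when adjusted over the list alone (camera adjusted p = 4.11e-26; adjusted p = 0.255 with an estimated correlation; fry adjusted p = 0.0221). Examples are the guanylate-binding protein gene Gbp3 (-1.85, SE 0.30, adjusted p = 0.0165), the tetherin gene Bst2 (-1.66, SE 0.30, adjusted p = 0.0212) and Oasl1 (-3.15, SE 0.59, adjusted p = 0.0225). Of the resident macrophage list, 2 of 17 measured members fell, Siglec1 and the receptor gene Axl (-1.80, SE 0.29, adjusted p = 0.0156), which takes part in clearing dying cells. The list as a whole had a median of -0.74 (camera adjusted p = 0.0534).

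NF-kB feedback genes were all positive at 3 weeks, with a median log2 fold change of 1.09. Of the 18, 7 rose over all genes and 14 did when adjusted over the list alone (camera adjusted p = 3.48e-16; adjusted p = 0.255 with an estimated correlation). They included Bcl3 (1.13, SE 0.16, adjusted p = 0.0112), the subunit gene Nfkb2 (1.27, SE 0.21, adjusted p = 0.0165), the adaptor gene Traf1 (1.60, SE 0.28, adjusted p = 0.0176) and the early response gene Ier3 (1.53, SE 0.32, adjusted p = 0.0312). Inflammatory mediators had a median of 0.69, with 2 of 28 rising over all genes, Ptgs2 and Ptges, and 10 rising and 1 falling when adjusted over the list alone (camera adjusted p = 4.23e-08; adjusted p = 0.255 with an estimated correlation). The interleukin 23 subunit gene Il23a stood at 1.53 against 0.356 CPM (adjusted p = 0.0517) and Saa3 at 159 against 27.1 CPM (adjusted p = 0.0534). Among Toll-like receptor and inflammasome genes, Irak3 rose (2.05, SE 0.32, adjusted p = 0.0144) and Tlr9, the receptor for unmethylated DNA, fell (-1.78, SE 0.31, adjusted p = 0.0174). The list median of 0.15 (camera adjusted p = 0.0197; adjusted p = 0.746 with an estimated correlation) was 0.03 without control replicate 2 and LPS replicate 2.

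Glycolysis and hypoxia genes were all positive at 3 weeks, with a median log2 fold change of 0.98. Of the 23, 4 rose over all genes and 11 did when adjusted over the list alone (camera adjusted p = 5.2e-14; adjusted p = 0.351 with an estimated correlation). The 4 were the hypoxia-inducible factor gene Hif1a (1.18, SE 0.26, adjusted p = 0.0381), the phosphofructokinase gene Pfkp (1.02, SE 0.23, adjusted p = 0.0382), with the vascular growth factor gene Vegfa (1.41, SE 0.32, adjusted p = 0.0395) and the lactate exporter gene Slc16a3 (0.89, SE 0.20, adjusted p = 0.0396). The list was also higher in numbered than in lettered libraries, by a median of 0.58. Its 3-week difference was 0.63 with the name series as a covariate and 0.42 among numbered libraries alone. Nuclear genes of oxidative phosphorylation had a median of -0.22, with 1 of 30 falling over all genes and 7 when adjusted over the list alone (camera adjusted p = 0.000491; adjusted p = 0.684 with an estimated correlation). The member that fell was the complex I gene Ndufa9 (-0.33, SE 0.08, adjusted p = 0.0431).

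Markers of other cell types moved as well. Eosinophil markers had a median of 0.68 (camera adjusted p = 0.00559; adjusted p = 0.746 with an estimated correlation). Ccr3 rose over all genes and 3 of 10 did when adjusted over the list alone, with Alox15 at 34.2 against 7.19 CPM (adjusted p = 0.0553). Of 10 measured endothelial genes, 3 fell: the vascular growth factor receptor genes Flt1 (-2.52, SE 0.45, adjusted p = 0.0193) and Kdr (-2.34, SE 0.52, adjusted p = 0.0378), and Vwf (-0.71, SE 0.15, adjusted p = 0.0341). The endothelial list had a median of -0.66 (camera adjusted p = 0.032; adjusted p = 0.255 with an estimated correlation), and -0.06 (adjusted p = 0.0866) among numbered libraries. Neutrophil genes had a median of 0.58 (camera adjusted p = 0.00224; adjusted p = 0.728 with an estimated correlation) with 0 of 19 past edgeR's threshold (14 were positive), and Lcn2 at 333 against 182 CPM (adjusted p = 0.122). In the proliferation list Pcna fell (-0.65, SE 0.16, adjusted p = 0.0489), and the list median of -0.82 (camera adjusted p = 0.032; adjusted p = 0.932 with an estimated correlation) was -0.10 without control replicate 2. Among numbered libraries it was 0.84 (adjusted p = 0.000582).

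Of the cytokine and bone-acting genes fixed beforehand, 0 passed edgeR's threshold at 3 weeks (DESeq2 and voom counts over all genes were 1998 and 776). Unadjusted p-values under 0.05 were found for Il1b (0.0444), Csf1r (0.0089) and Nos2 (0.00554). Nos2 stood at 685 ± 21.2 against 61.6 ± 75.2 CPM, an 11.2-fold difference (adjusted p = 0.0721). Among controls Nos2 was 148 CPM in the numbered library and 13.2 and 23.2 in the lettered ones. As all 3-week libraries are numbered, the lettered controls enlarge this fold difference. Il1b stood at 304 ± 7.07 against 92 ± 40.9 (adjusted p = 0.176). Tnf was 2.63-fold above controls (log2 fold change 1.39, SE 0.68, adjusted p = 0.211) and Il6 stood at 11.2 ± 0.437 against 8.01 ± 2.15 (adjusted p = 0.452). Csf1r stood at 2040 ± 15.5 against 1120 ± 468 CPM (adjusted p = 0.0868) and Adgre1 at 529 ± 1.96 against 409 ± 108 (adjusted p = 0.308). The macrophage core list that holds both had a median log2 fold change of -0.45, with 1 of 22 members falling (camera adjusted p = 0.34). Igf1 stood at 24 ± 1.77 against 49.1 ± 16.4 (adjusted p = 0.21), Osm at 104 ± 15.5 against 95.9 ± 27.9 (adjusted p = 0.788) and Arg1 at 808 ± 4.72 against 611 ± 205 (adjusted p = 0.782). Of the 19 measured bone-acting secreted factors, Vegfa alone rose, and the list as a whole had a median of 0.12 (camera adjusted p = 0.414). That median was 0.62 (adjusted p = 0.00045) with the name series as a covariate and 0.57 (adjusted p = 0.0103) among numbered libraries.

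In all, 563 genes changed at 3 weeks, 328 higher and 235 lower, 282 of them by at least 2-fold. Groups did not overlap for 34.7% of genes, against 10% by chance. The 10% takes all libraries compared as independent. If the 3-week libraries share a source, the share by chance is higher, and 34.7% need not exceed it. With DESeq2's size factors the split was 442 higher and 189 lower, a share of 70% higher against 58.3%. All 3-week libraries are numbered: among numbered libraries, with 1 control, 95 genes changed, 30 higher and 65 lower (31.6% higher). List medians there were -1.88 for interferon, 0.67 for NF-kB, 0.45 for inflammatory mediators, 1.95 for eosinophil and 1.06 for neutrophil genes. They were -0.16 for oxidative phosphorylation, 0.03 for Toll-like receptor and -0.70 (adjusted p = 0.00525) for resident macrophage genes. Summed to 1 library, which removes replication from this group, it gave 0 changed genes (896 at an unadjusted p under 0.05), with medians of -1.81 for interferon, 1.13 for NF-kB, 1.02 for glycolysis and 0.75 for inflammatory genes. Without each of its 3 libraries in turn the count was 15, 19 and 19, and without control replicate 3 it was 33. A block by the last character of the library name left 4 genes, 0 of them among the 563.

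**Figure D2:**
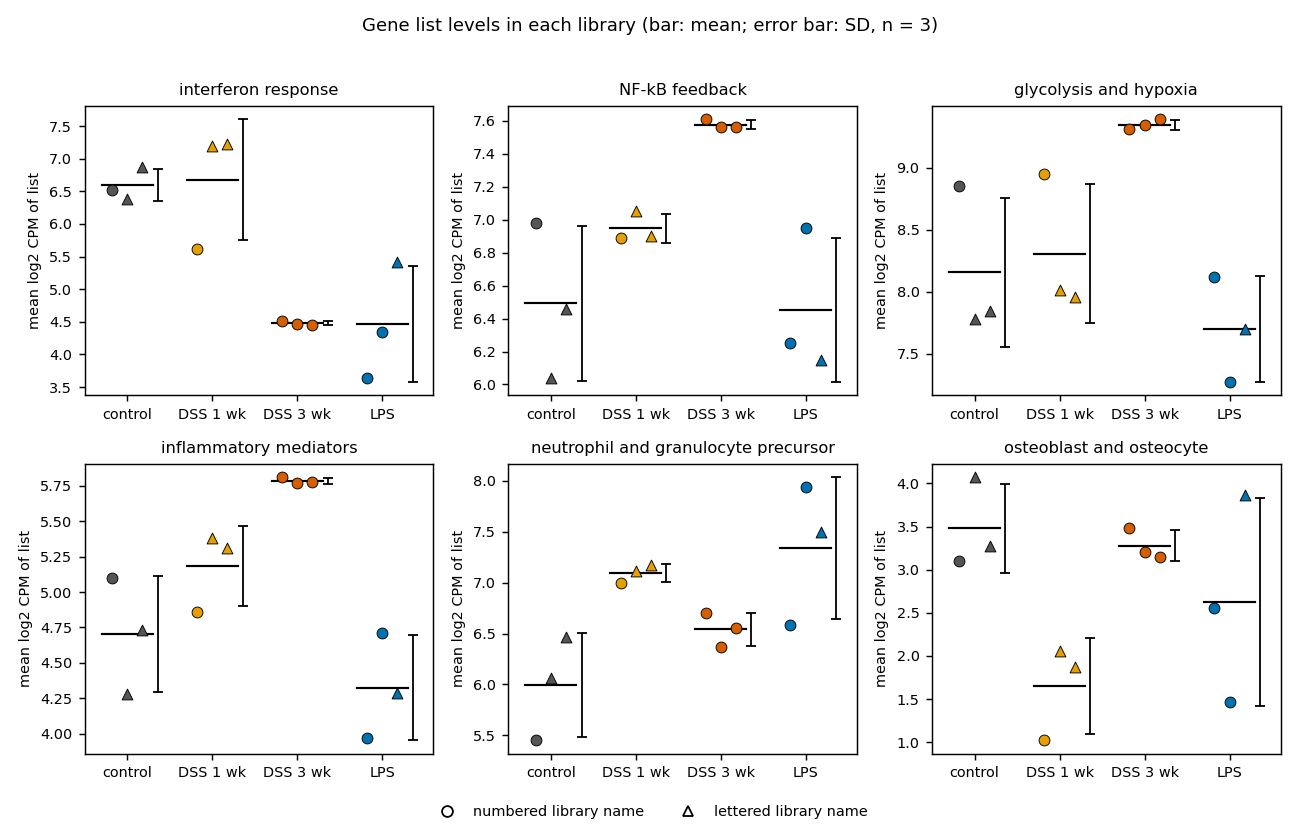
Mean log2 CPM of 6 gene lists in each library, with bars for group means and error bars for SD (n = 3), circles for numbered and triangles for lettered library names. The interferon list lies at 4.45 to 4.51 at 3 weeks after DSS against 6.39 to 6.87 in controls, and the NF-kB list at 7.56 to 7.61 against 6.04 to 6.98.

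At 3 days after LPS, stefin genes and Saa3 rose against controls, and some genes induced by interferon fell. The interferon list, with 1 of 29 members past the threshold, passed with a preset correlation but not with an estimated one (adjusted p = 0.163 with an estimated correlation). Cstdc5 rose 112-fold, from 0.26 ± 0.145 to 29 ± 6.82 CPM (SD, n = 3 each; log2 fold change 6.80, SE 0.53, adjusted p = 0.000804), and Stfa2 47.8-fold, from 0.361 ± 0.127 to 17.4 ± 7.2 CPM (log2 fold change 5.58, SE 0.50, adjusted p = 0.00165). Saa3 rose 12.2-fold, from 27.1 ± 21.1 to 331 ± 294 CPM (log2 fold change 3.61, SE 0.68, adjusted p = 0.0479). Ifi205 (gene 226695, chromosome 1, 173839549 to 173859617), an interferon-activated gene also in the monocyte list, was 7.84-fold lower, at 3.82 ± 2.12 against 30 ± 10.5 CPM (log2 fold change -2.97, SE 0.46, adjusted p = 0.0429). Bst2 was 3.2-fold lower, at 94.5 ± 45 against 303 ± 27.4 CPM (log2 fold change -1.68, SE 0.30, adjusted p = 0.0458).

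Further stefin genes rose after LPS: Stfa1 by 47.1-fold (adjusted p = 0.00978) and Stfa3 by 12.2-fold (adjusted p = 0.0429). So did Cstdc4 by 7.26-fold (adjusted p = 0.0422) and Stfa2l1 by 6.83-fold (adjusted p = 0.0323). Asprv1 rose 5.08-fold, from 19.7 ± 5.28 to 100 ± 53.8 CPM (adjusted p = 0.0429). Other genes that fell were the Ly6 family gene Ly6i (6.88-fold lower, adjusted p = 0.0176), Ms4a4c (5.59-fold lower, adjusted p = 0.0429) and Phf11d (5.44-fold lower, adjusted p = 0.0447). Further ones were the Schlafen gene Slfn8 (3.5-fold lower, adjusted p = 0.0458) and the interferon-induced genes Ifi27l2a (5.48-fold lower, adjusted p = 0.0429) and Ifi211 (4.03-fold lower, adjusted p = 0.0449).

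All 29 interferon response genes were lower after LPS, with a median log2 fold change of -1.89. Over all genes 1 fell, Bst2, and 27 did when adjusted over the list alone (camera adjusted p = 1.97e-44; adjusted p = 0.163 with an estimated correlation; fry adjusted p = 0.0406). Irf7, the factor that amplifies type I interferon production, stood at 70.2 against 470 CPM (adjusted p = 0.0531), the RNA sensor gene Ifih1 at 42.3 against 110 (adjusted p = 0.0556) and Mx2 at 4.33 against 31.2 (adjusted p = 0.0656). All 19 neutrophil and granulocyte precursor genes were higher, with a median of 1.16. Of these, Stfa2 and Stfa2l1 rose over all genes and 8 did when adjusted over the list alone (camera adjusted p = 2.56e-19; adjusted p = 0.138 with an estimated correlation). Lcn2 stood at 596 against 182 CPM (adjusted p = 0.0517) and Ly6g at 9.76 against 3.18 (adjusted p = 0.0795). Without control replicate 2 and LPS replicate 2 the neutrophil median was 0.57 (camera adjusted p = 3.64e-11).

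Inflammatory mediators had a median of -0.45 after LPS, with Saa3 rising and Ptgs2 falling over all genes and 1 rising and 4 falling when adjusted over the list alone (camera adjusted p = 0.00192; adjusted p = 0.42 with an estimated correlation). Ptgs2 stood at 38.4 against 90.7 CPM (log2 fold change -1.24, SE 0.21, adjusted p = 0.0441), the chemokine gene Ccl5 at 5.66 against 19 (adjusted p = 0.0867) and Osm at 48 ± 8.3 against 95.9 ± 27.9 (adjusted p = 0.115). Tnf stood at 85.4 ± 105 against 38.3 ± 9.32 CPM (adjusted p = 0.481), a mean set by 206.54 CPM in LPS replicate 2. Il1b stood at 56.7 ± 52.3 against 92 ± 40.9 CPM (adjusted p = 0.733), Il6 at 3.84 ± 2.38 against 8.01 ± 2.15 (adjusted p = 0.274) and Nos2 at 42.6 ± 38.6 against 61.6 ± 75.2 (adjusted p = 0.852). Adgre1 stood at 480 ± 145 against 409 ± 108 CPM (adjusted p = 0.703), Csf1r at 1040 ± 249 against 1120 ± 468 (adjusted p = 0.909), Igf1 at 77.1 ± 50.1 against 49.1 ± 16.4 (adjusted p = 0.607) and Arg1 at 453 ± 523 against 611 ± 205 (adjusted p = 0.869).

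Lists of metabolism and of other cell types moved after LPS as well. Monocyte genes had a median of -0.32, with Ms4a4c and Ifi205 falling over all genes and 3 of 14 when adjusted over the list alone (camera adjusted p = 0.00385; adjusted p = 0.352 with an estimated correlation). Glycolysis and hypoxia genes had a median of -0.44 with 22 of 23 negative (camera adjusted p = 1.74e-05; adjusted p = 0.558 with an estimated correlation). The phosphofructokinase gene Pfkl is an example (-0.76, SE 0.22, adjusted p = 0.174). Osteoclast genes had a median of 0.53 (camera adjusted p = 0.0258; adjusted p = 0.558 with an estimated correlation), but 0.03 between the numbered libraries. The proton pump gene Atp6v0d2 stood at 91.2 against 29.2 CPM (adjusted p = 0.276) and the integrin gene Itgb3 at 25.7 against 14.3 (adjusted p = 0.27). B lineage genes had a median of -1.59 with 1 of 16 rising and 7 falling when adjusted over the list alone (camera adjusted p = 2.33e-05; adjusted p = 0.558 with an estimated correlation). Their median was 0.12 between the numbered libraries. Dendritic cell genes had a median of -1.23 (camera adjusted p = 0.000175; adjusted p = 0.381 with an estimated correlation) with Bst2 as the member that fell. Dissociation stress genes, an early response to tissue digestion, had a median of -0.30 (camera adjusted p = 0.000175; adjusted p = 0.263 with an estimated correlation). Bone-acting secreted factors had a median of -0.39 (camera adjusted p = 0.0407; adjusted p = 0.42 with an estimated correlation), but -0.13 (adjusted p = 0.233) with the name series as a covariate and 0.13 (adjusted p = 0.341) without control replicate 2 and LPS replicate 2. Between numbered libraries, with 1 control, medians were -2.28 for interferon, 1.96 for neutrophil, -0.55 for inflammatory, -0.93 for glycolysis and -0.82 for monocyte genes. They were -0.62 for dendritic cell, -0.41 for dissociation stress and -0.03 for bone-acting genes.

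In all, 79 genes changed after LPS, 41 higher and 38 lower, and 11.7% of genes had no overlap between the groups, against 10% by chance. With upper quartile scaling the split was 43 higher and 24 lower, a share of 64.2% higher against 51.9%. Without control replicate 2 and LPS replicate 2 the count was 132, of which 40 were among the 79. It was 554 with DESeq2, with all 79 among them, and 1 when only the 6 libraries compared were fitted. Leaving out any of the 3-week DSS libraries, which enter through the shared spread, gave 4.

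**Figure D3:**
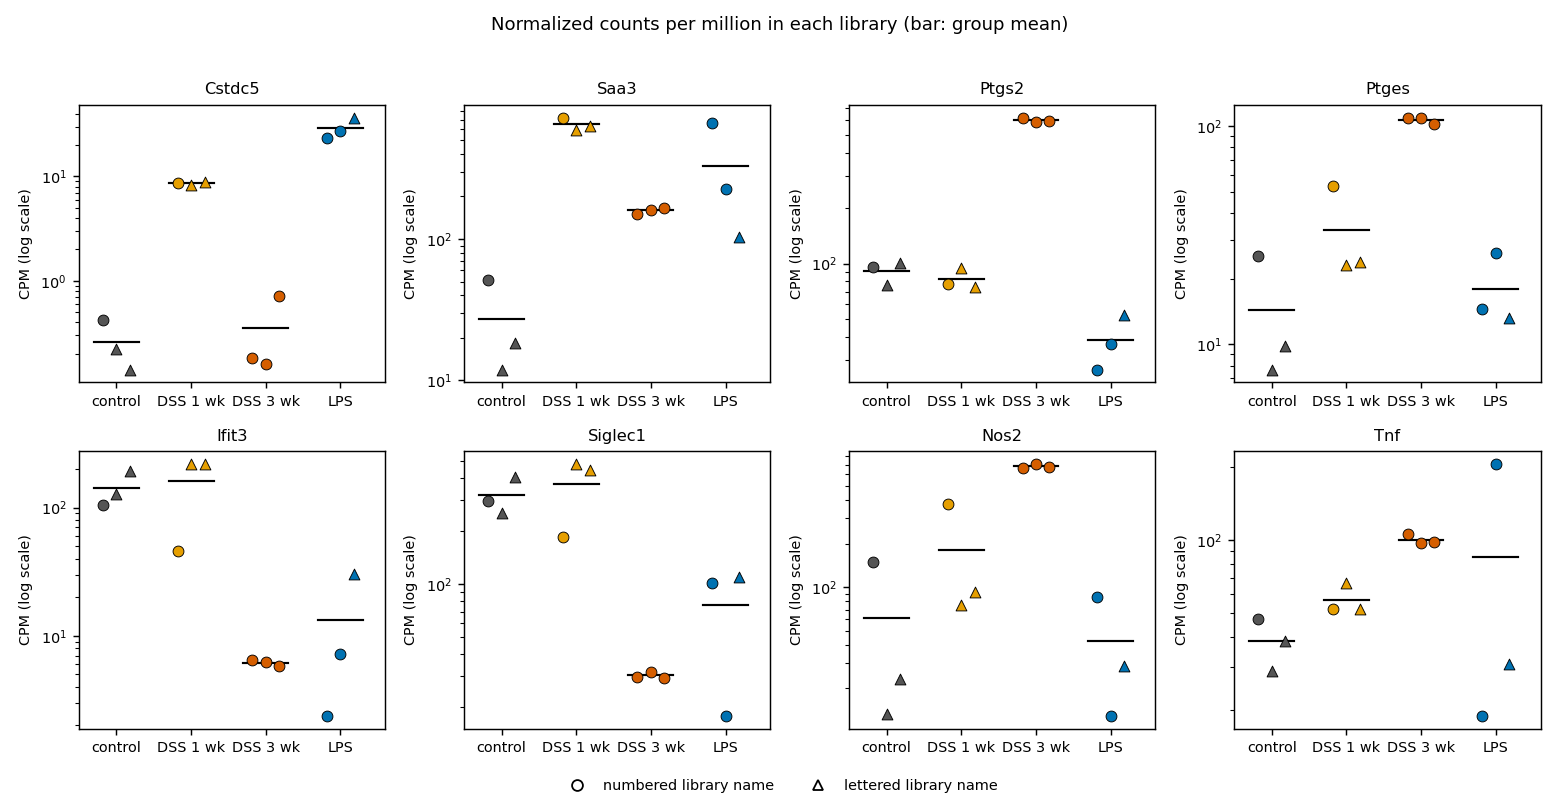
Normalized CPM of 8 genes in each library on a log scale, with bars for group means, circles for numbered and triangles for lettered library names. Ptgs2 lies at 589 to 620 CPM at 3 weeks after DSS and at 74.8 to 100 CPM in controls and at 1 week, while Cstdc5 lies at 8.25 to 36.5 CPM at 1 week and after LPS and at or under 0.72 CPM elsewhere.

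Between 1 and 3 weeks after DSS, interferon-induced genes and the stefins Stfa2, Stfa2l1 and Cstdc5 were lower at the later time, while Ptgs2 and some genes of the eosinophil, osteoblast and chondrocyte lists were higher. These lists and the interferon list passed with a preset correlation but not with an estimated one (adjusted p = 0.352 with an estimated correlation for each). Ptgs2 was 7.32-fold higher at 3 weeks, at 602 ± 15.7 against 82.3 ± 10.5 CPM (SD, n = 3 each; log2 fold change 2.87, SE 0.22, adjusted p = 0.000722). The matrix protease gene Mmp3 (gene 17392, chromosome 9, 7445822 to 7455975) was 19-fold higher, at 108 ± 6.24 against 5.62 ± 4.64 CPM (log2 fold change 4.24, SE 0.93, adjusted p = 0.0275). Stfa2 was 40-fold lower, at 0.206 ± 0.17 against 8.37 ± 0.989 CPM (log2 fold change -5.32, SE 0.52, adjusted p = 0.00168), and Cstdc5 24.7-fold lower, at 0.352 ± 0.32 against 8.62 ± 0.349 CPM (log2 fold change -4.63, SE 0.49, adjusted p = 0.00208).

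Other genes that were higher at 3 weeks were Col1a2 (14.2-fold, adjusted p = 0.036), Alox15 (14-fold, adjusted p = 0.0124), and the hyaluronan-degrading gene Cemip (11.7-fold, adjusted p = 0.0414). Others were the joint lubricant gene Prg4 (10.7-fold, adjusted p = 0.0167), the incretin receptor gene Gipr (9.11-fold, adjusted p = 0.0481) and Ccr3 (8.62-fold, adjusted p = 0.0054). Genes that were lower included Ifit3b (32-fold, adjusted p = 0.0189), Ifit3 (26-fold, adjusted p = 0.0167), and Ifit1bl1 (25.6-fold, adjusted p = 0.0363), as well as Ifit2 (19.5-fold, adjusted p = 0.0155), Ifi208 (15.8-fold, adjusted p = 0.0431) and Ifi44 (12.6-fold, adjusted p = 0.0269). All 29 interferon response genes were lower, with a median log2 fold change of -2.29. Of these, 25 fell over all genes and 29 did when adjusted over the list alone (camera adjusted p = 4.61e-32; adjusted p = 0.352 with an estimated correlation). The median was -1.10 between the numbered libraries and -1.64 with the name series as a covariate. The guanylate-binding protein gene Gbp2 stood at 14.1 against 75.4 CPM (adjusted p = 0.0121) and the immunity-related GTPase gene Irgm1 at 45.3 against 159 CPM (adjusted p = 0.0133).

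Of 22 macrophage core genes, 4 fell between 1 and 3 weeks over all genes and 10 did when adjusted over the list alone, with a median of -0.70 (camera adjusted p = 5.03e-06; adjusted p = 0.352 with an estimated correlation). These 4 were the lysosomal protease gene Ctss (-1.28, SE 0.24, adjusted p = 0.0173), the lysosomal membrane genes Cd63 (-0.74, SE 0.14, adjusted p = 0.018) and Cd68 (-0.98, SE 0.22, adjusted p = 0.0269), and the Fc receptor gene Fcgr1 (-1.66, SE 0.41, adjusted p = 0.042). NF-kB feedback genes were all positive with a median of 0.56, 3 of 18 rising over all genes and 5 when adjusted over the list alone (camera adjusted p = 5.03e-06; adjusted p = 0.352 with an estimated correlation). They included Ier3 (1.34, SE 0.32, adjusted p = 0.0365) and Traf1 (1.12, SE 0.27, adjusted p = 0.0411). Glycolysis and hypoxia genes had a median of 0.70, 4 of 23 rising over all genes and 6 when adjusted over the list alone (camera adjusted p = 8.81e-10; adjusted p = 0.352 with an estimated correlation). Among them were Hif1a (1.27, SE 0.26, adjusted p = 0.0236) and Pfkfb3 (1.09, SE 0.28, adjusted p = 0.0489). The glycolysis median was 0.33 with the name series as a covariate and 0.30 between the numbered libraries. Oxidative phosphorylation genes had a median of -0.19, 6 of 30 falling over all genes and 7 when adjusted over the list alone (camera adjusted p = 7.63e-05; adjusted p = 0.352 with an estimated correlation). Of these, 3 encode subunits of succinate dehydrogenase, Sdha, Sdhb and Sdhc, with log2 fold changes of -0.44, -0.45 and -0.48 (adjusted p = 0.0252, 0.0478 and 0.0397). Inflammatory mediators had a median of 0.48, with Ptgs2 rising and Ccl5 falling over all genes (camera adjusted p = 0.00111; adjusted p = 0.352 with an estimated correlation).

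Eosinophil markers had a median of 2.06 between 1 and 3 weeks, with 3 of 10 rising over all genes and 7 when adjusted over the list alone (camera adjusted p = 1.89e-08; adjusted p = 0.352 with an estimated correlation). Over all genes these were Ccr3, Alox15 and Ear1 (2.54, SE 0.54, adjusted p = 0.0252). Osteoblast and osteocyte genes had a median of 2.04, 3 of 9 rising and 1 falling over all genes and 6 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.00244; adjusted p = 0.352 with an estimated correlation). Runx2, the master transcription factor of osteoblasts, rose (0.85, SE 0.18, adjusted p = 0.026) with Col1a1 (2.04, SE 0.47, adjusted p = 0.0315) and Col1a2, while Spp1, the osteopontin gene that macrophages also express, fell (-2.65, SE 0.46, adjusted p = 0.0149). Of 5 measured chondrocyte genes Prg4 rose, and the list had a median of 1.28 (camera adjusted p = 0.00783; adjusted p = 0.352 with an estimated correlation). In the neutrophil list, Stfa2, Stfa2l1 and Ly6g (-1.65, SE 0.34, adjusted p = 0.0236) fell, with a median of -0.29 over the 19 (camera adjusted p = 0.0115; adjusted p = 0.489 with an estimated correlation). In the dissociation stress list the chaperone gene Dnajb1 rose (0.39, SE 0.10, adjusted p = 0.0465), with a list median of 0.28 (camera adjusted p = 0.0137; adjusted p = 0.352 with an estimated correlation).

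Between numbered libraries, with 1 from 1 week, medians were -0.62 for macrophage core, 0.70 for NF-kB, 0.87 for inflammatory, -0.26 for oxidative phosphorylation and 2.92 for eosinophil genes. They were 3.57 for osteoblast, 1.85 (adjusted p = 0.0581) for chondrocyte, -0.20 for neutrophil and 0.29 for dissociation stress genes.

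In all, 851 genes differed between 1 and 3 weeks, 342 higher and 509 lower at the later time, 404 of them by at least 2-fold. Groups did not overlap for 44.7% of genes, against 10% by chance. Here too the 10% takes the libraries as independent, and it is too low if the 3-week libraries share a source. Scaled by total counts alone the split was 650 higher and 428 lower, a share of 60.3% higher against 40.2%. With the 3-week libraries summed to 1, which removes replication from that group, the count was 0, with list medians of -2.29 for interferon and 2.08 for eosinophil genes. The count was 47 between the numbered libraries, 23, 28 and 25 without each 3-week library in turn, and 22 and 32 without replicate 2 or 3 from 1 week.

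The responses to LPS and to DSS were set against each other directly. At 3 weeks after DSS, most glycolysis and hypoxia genes and some inflammatory and antigen presentation genes were higher than after LPS. Their lists passed with a preset correlation but not with an estimated one (adjusted p = 0.21, 0.21 and 0.589 with an estimated correlation). Of 23 glycolysis and hypoxia genes, 17 were higher over all genes and 22 when adjusted over the list alone (median log2 difference 1.29, camera adjusted p = 4.42e-24; adjusted p = 0.21 with an estimated correlation). Vegfa stood at 667 against 123 CPM (adjusted p = 0.00328) and Slc16a3 at 707 against 243 (adjusted p = 0.00314). Of 28 inflammatory mediators, 11 were higher (median 1.13, camera adjusted p = 3.94e-13; adjusted p = 0.21 with an estimated correlation). Among them were Ptgs2 (3.97, SE 0.23, adjusted p = 4.41e-05), the chemokine gene Cxcl3 (3.63, SE 0.73, adjusted p = 0.0143) and the costimulatory receptor gene Cd40 (1.72, SE 0.35, adjusted p = 0.0148). NF-kB feedback genes were higher in 10 of 18 (median 0.97, camera adjusted p = 2.26e-14; adjusted p = 0.21 with an estimated correlation). MHC class II genes were higher in 5 of 12 (median 0.65, camera adjusted p = 0.0147; adjusted p = 0.589 with an estimated correlation), including the presenting chain gene H2-Ab1 at 296 against 99.6 CPM (adjusted p = 0.0107) and Cd74 at 804 against 309 (adjusted p = 0.0292).

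Markers of other cells and of tissue digestion moved with these. Dissociation stress genes were higher at 3 weeks than after LPS in 5 of 20 (median 0.43, camera adjusted p = 5.04e-05; adjusted p = 0.21 with an estimated correlation). Dendritic cell genes had a median of 1.05 (adjusted p = 0.019; adjusted p = 0.582 with an estimated correlation) and monocyte genes of 0.47 (adjusted p = 0.0189; adjusted p = 0.377 with an estimated correlation). Eosinophil genes had a median of 0.39 (adjusted p = 0.0364; adjusted p = 0.597 with an estimated correlation) and neutrophil genes of -0.93 (adjusted p = 0.00275; adjusted p = 0.582 with an estimated correlation).

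At 1 week after DSS, interferon response genes were higher than after LPS, 4 of 29 over all genes and 27 when adjusted over the list alone (median 2.15, camera adjusted p = 4.95e-53; adjusted p = 0.113 with an estimated correlation). The 4 were Bst2 (1.75, SE 0.30, adjusted p = 0.0471), Ifih1 (1.58, SE 0.27, adjusted p = 0.0471), Irgm1 (1.66, SE 0.30, adjusted p = 0.0493) and Irf7 (2.88, SE 0.53, adjusted p = 0.0493). Of 14 monocyte genes, Ms4a4c (2.62, SE 0.38, adjusted p = 0.037) and Ifi205 (3.08, SE 0.46, adjusted p = 0.037) were higher (list median 0.63, camera adjusted p = 6.79e-08; adjusted p = 0.0783 with an estimated correlation). Other lists moved with these: dissociation stress (0.10, adjusted p = 0.00994), dendritic cell (0.74, adjusted p = 0.000943), eosinophil (-1.63, adjusted p = 1.09e-05) and proliferation genes (-1.33, adjusted p = 3.45e-11), each with an adjusted p = 0.305 with an estimated correlation. B lineage genes had a median of 1.42 (adjusted p = 0.000578; adjusted p = 0.443 with an estimated correlation). Their mean log2 CPM in lettered libraries was 2.73 and 2.9 at 1 week against 1.42 after LPS. In numbered libraries it was 0.44 at 1 week, between the 1.53 and 0.15 after LPS. Counting all genes, 1314 differed between 3 weeks of DSS and LPS, 742 higher and 572 lower after DSS, and 70 differed between 1 week of DSS and LPS, 62 higher and 8 lower. The former count was 290, 289 and 287 without each 3-week library in turn and 3 with these summed to 1. The latter count was 0 without 1-week replicate 2 or 3, 1 without any of the 3-week libraries, and 9 or 5 with upper quartile scaling or total counts. Without LPS replicate 2 it was 60, with 27 higher and 33 lower, and 16 of these were among the 70. Of all list calls in the 6 comparisons, 0 held with an estimated correlation, the lowest adjusted p being 0.0783. The fry test, with its own adjustment, called some lists. At 3 weeks against control these included NF-kB (0.0111), inflammatory (0.0152), glycolysis (0.032), oxidative phosphorylation (0.0111) and endothelial genes (0.0111). After LPS they included neutrophil (0.0406) and dissociation stress genes (0.0468). Between 3 weeks and 1 week they included interferon (0.0358), oxidative phosphorylation (0.0165) and eosinophil genes (0.047), and between 1 week and LPS interferon (0.043) and monocyte genes (0.0285). Between 3 weeks and LPS they included inflammatory (0.00863), NF-kB, glycolysis, dissociation stress and endothelial (0.00889 each), oxidative phosphorylation (0.0156), monocyte (0.0473) and bone-acting genes (0.0486).

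Fold changes against the common controls were correlated across genes, which are not independent replicates. Between 1 week of DSS and LPS the correlation was 0.64, against 0.49 simulated for unchanged groups sharing these controls. The covariance was 0.36 against 0.1, a difference of 0.26. Between 1 and 3 weeks of DSS it was 0.56 against 0.5, with covariances of 0.34 and 0.1. Between 3 weeks of DSS and LPS it was 0.52 against 0.49, with covariances of 0.29 and 0.1. The simulation holds no effect of the name series, and with that as a covariate the correlations, in the order above, were 0.49, 0.22 and 0.35. It also gives each gene 1 spread in all libraries, while the real controls varied most. Their median coefficient of variation per gene was 0.158, against 0.08 at 1 week, 0.028 at 3 weeks and 0.124 after LPS. Noisier shared controls raise the correlation of unchanged groups, so the simulated values can be too low. Without control replicate 2 the correlations were 0.35, 0.17 and 0.33, and the 3 controls are too few to split. Part or all of the excess may therefore come from shared controls, and no shared response is concluded. Both genes that rose at 1 week also rose after LPS (independent lists would share 0.00565). Both at 3 weeks and after LPS, 2 genes were higher and 19 lower (independent lists would share 0.926 and 0.615), while 5 changed in opposite directions. The figures for independent lists do not allow for the shared controls. The simulation of unchanged groups, with the limits above, gave 0 shared genes on average for each pair.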

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

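For the patterns weighed here, the tests on abundant genes and on name series and the regroupings of libraries were set before the values were seen, while the tests of the similar 3-week libraries were chosen after seeing the results.

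A direct test of whether the responses against control differed gave 851 genes between 3 weeks and 1 week of DSS. It gave 1314 genes between 3 weeks of DSS and LPS, and 70 between 1 week of DSS and LPS. Each comparison of 3 with 3 libraries allows 10 splits, too few for a share under 0.05, so the number of splits with as many genes as the real grouping, 1 of 10 in all 6 comparisons, cannot fall lower. For 1 week, 3 weeks and LPS against control the real groupings gave 2, 563 and 79 genes, and the highest other split gave 0 each time. The highest other split was also 0 for the 851 and the 1314 genes and was 2 for the 70 genes.

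Glycolysis and hypoxia genes such as Hif1a and Pfkp were higher at 3 weeks after DSS than in controls, with a list median log2 fold change of 0.98 and 4 of 23 genes past the threshold (adjusted p = 0.351 with an estimated correlation). A few abundant genes taking most counts could produce such a shift. The 50 most abundant genes of each library took 16% to 16.4% of counts at 3 weeks and 13.4% to 17.3% in controls, which argues against that. Without the 50 most abundant genes the median was 1.03. That value adds little, since scaling by trimmed mean of M values already limits the pull of such genes. A batch marked by the numbered and lettered library names could also contribute. With the name series as a covariate the median was 0.63 and among numbered libraries, with 1 control, 0.42. The batch and a metabolic response to colitis cannot be told apart, as all 3-week libraries are numbered. Their names also have a format of their own, and neither setting could correct for a batch marked by that format.

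The libraries from 3 weeks after DSS differed less from each other than libraries of the other groups did. Their median coefficient of variation per gene of 0.028, against 0.158 in controls, 0.08 at 1 week and 0.124 after LPS, does not decide whether 1 RNA pool or animal was split into 3 libraries. The bound set for this test, 0.1, is also met by the 1-week group, so a shared source and mice that respond alike cannot be told apart. Deeper sequencing as the whole cause is argued against. The coefficient above leaves counting noise out. A plain coefficient that keeps this noise was 0.043 at 3 weeks and 0.089 at 1 week, the closest other group, at full depth. With counts thinned to the smallest total the plain coefficient was 0.047 and 0.091, and at least 96% of the gap at full depth was left. If the 3 libraries share a source, the p-values of their comparisons could be too small. So could those of the other comparisons, since all groups share 1 estimate of spread. Leaving out any of the 3-week libraries took LPS against control from 79 genes to 4. It took 1 week of DSS against LPS from 70 genes to 1, while 1 week against control stayed at 2.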

How the results depend on the processing

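Of the named genes, 0 that passed with or without an alternative setting changed direction under it. Many lost their call, though. Of the 16 genes named for the largest changes at 3 weeks, 2, 2 and 3 passed without each 3-week library in turn. With the block by name suffix 0 of them passed. Of the 16 named after LPS, 3 passed on leaving out any of the 3-week libraries. When only the 6 libraries compared were fitted, 1 did. Counts of calls moved with most settings, and a larger count did not always hold all main calls. Genes with few counts are limited by depth, and without the filter on low counts 5, 364, 507 and 32 genes passed for 1 week of DSS, 3 weeks of DSS, 3 weeks against 1 week and LPS. Where no reason is given below, the cause was not tested.

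Scaling by upper quartile gave 9 genes between 1 week of DSS and LPS and scaling by total counts 5, against 70. DESeq2 called 3091 genes in any group, 240 and 1998 for 1 and 3 weeks of DSS, 554 for LPS, 1744 between 3 weeks and 1 week, 412 between 1 week and LPS and 2250 between 3 weeks and LPS. Limma voom called 0 genes at 1 week (1587 unadjusted). With sample weights voom called 7282 genes in any group, 824, 5809 and 697 against control, 6435 between 3 weeks and 1 week, and 2288 and 6083 against LPS.

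Fits to only the groups compared gave 0 genes at 1 week, 1 for LPS, 3772 between 3 weeks and 1 week and 0 between 1 week of DSS and LPS. Lettered libraries alone gave 1 gene at 1 week, which was not among the 2 called in the main fit. With the name series as a covariate the counts were 21, 328 and 153 against control. They were 641 between 3 weeks and 1 week and 222 between 1 week and LPS. Of the 563 genes called at 3 weeks in the main fit 213 still passed, and of the 851 between 3 weeks and 1 week 375 did. Of the 79 called for LPS 75 still passed, as did all 70 between 1 week and LPS. The direction of B lineage genes then turned, with medians of 0.79 at 3 weeks against control and 1.00 against 1 week.

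Whether the replicate numbers pair the libraries is not settled. Of 18 same-numbered pairs 6 had a correlation of deviations over 0.1, against 4 of 36 other pairs, with a median of 0 for both. The lowest same-numbered value was -0.13, and 5 of 12 libraries correlated best with their own number. All pairs over 0.1 lay within a name series, so number and series cannot be told apart here. With the replicate block 6, 954 and 21 genes passed for 1 week, 3 weeks and LPS, and the correlations of effects were 0.43 between 1 and 3 weeks and 0.41 between 3 weeks and LPS. Of 10 pairs whose library names end in the same character, 5 had a correlation of deviations over 0.1. A block by the last character of the library name left 13 genes in any group and 0, 4 and 5 against control. It left 28 between 3 weeks and 1 week, and 0 and 140 for 1 and 3 weeks against LPS. B lineage medians were 0.79 and 1.19 under this block.

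Without control replicate 2 and LPS replicate 2, a setting added after seeing the data, 2804 genes passed in any group. The counts were 29, 1168 and 132 against control, 2755 between 3 weeks and 1 week, and 323 and 2738 for 1 and 3 weeks against LPS, and the proliferation median at 3 weeks was -0.10. With the 3-week libraries summed to 1, which leaves 10 libraries, 3 genes passed in any group. The counts were 0 at 3 weeks, 3 for LPS, 0 between 3 weeks and 1 week, 0 between 1 week and LPS and 3 between 3 weeks and LPS. Numbered libraries alone, 7 in all, gave 510 genes in any group, 0, 95 and 159 against control, 47 between 3 weeks and 1 week and 38 between 1 week and LPS.

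Lists whose direction in camera turned between the numbered libraries are given with their medians. At 1 week these were inflammatory mediators (-0.28), interferon (-0.86), NF-kB (-0.02), Toll-like receptor (-0.02) and proliferation genes (0.61). At 3 weeks these were proliferation (0.84), Toll-like receptor (0.03) and B lineage genes (1.05, and 1.56 against 1 week). After LPS they were macrophage core (-0.18) and osteoclast genes (0.03).

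Correlations of effects between 1 and 3 weeks of DSS, 1 week and LPS, and 3 weeks and LPS were 0.73, 0.75 and 0.72 without the filter and 0.33, 0.51 and 0.32 with voom. They were 0.27, 0.30 and 0.34 with voom weights, 0.22, 0.49 and 0.35 with the name series as a covariate and 0.22, 0.53 and 0.35 with the suffix block. Without control replicate 2 and LPS replicate 2 they were 0.16, 0.31 and 0.31, and with the 3-week libraries summed 0.84, 0.87 and 0.83. Among numbered libraries the former pair were 0.32 and 0.48, and for genes of at least 10 CPM the latter pair were 0.52 and 0.41.

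Leaving out each library in turn gave 47 (without 3-week replicate 1) to 2593 genes (without control replicate 1) in any group. The range was 0 (without 1-week replicate 3, 1321 unadjusted) to 37 (without LPS replicate 2) at 1 week, 15 (without 3-week replicate 1) to 2680 (without control replicate 1) at 3 weeks, and 4 (without 3-week replicate 1) to 141 (without LPS replicate 3) for LPS. It was 22 (without 1-week replicate 2) to 1585 (without control replicate 2) between 3 weeks and 1 week. Against LPS it was 0 (without 1-week replicate 2 or 3) to 195 (without 1-week replicate 1) for 1 week and 287 (without 3-week replicate 3) to 2315 (without control replicate 2) for 3 weeks. The correlations ranged from 0.17 to 0.70, 0.35 to 0.75 and 0.33 to 0.66, the lowest without control replicate 2 and the highest without control replicate 1. The direction in camera of proliferation and resident macrophage genes turned when certain libraries were left out. The proliferation median at 3 weeks ranged from -1.19 (without control replicate 1) to -0.10 (without control replicate 2, turned). After LPS it ranged from -0.43 (without LPS replicate 2, turned) to 1.03 (without control replicate 2), with -0.10 (turned) without control replicate 1. That of resident macrophage genes ranged from -0.47 (without LPS replicate 1, turned) to 0.92 (without LPS replicate 2).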

Other observations

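The stefin test below was chosen after seeing the results, and the other values in this part were not weighed against explanations.

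Transcripts of lymphoid, mast and dendritic cells, which an F4/80 sort is meant to exclude, differed between the numbered and the lettered libraries. B lineage and plasma cell genes, such as the antigen receptor component Cd79a and the B cell factor Pax5, were lower in numbered than in lettered libraries by a median of -1.72 on the log2 scale (camera adjusted p = 1.88e-14; adjusted p = 0.276 with an estimated correlation). With an estimated correlation 0 lists passed camera here, the lowest adjusted p being 0.276. Mast cell and basophil genes differed by -1.05 (adjusted p = 0.000912), T and NK cell genes by -0.96 (adjusted p = 0.0475) and dendritic cell genes by -0.60 (adjusted p = 0.000712). Osteoblast and osteocyte genes differed by -0.91 (adjusted p = 0.000264), and marrow stroma genes by -0.61 (adjusted p = 0.000581). MHC class II genes, which macrophages share with B and dendritic cells, differed by -0.51 (adjusted p = 0.00147). Interferon response genes differed by -0.96 (adjusted p = 3.73e-21), eosinophil genes by -0.82 (adjusted p = 0.00418), neutrophil genes by -0.41 (adjusted p = 0.0256) and NF-kB genes by 0.36 (adjusted p = 0.000204).

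After LPS, smaller lists moved too. Erythroid genes had a median log2 fold change of -2.61 over 4 measured members (camera adjusted p = 0.0225; adjusted p = 0.42 with an estimated correlation). MHC class II genes had a median of -0.33 (adjusted p = 0.0258; adjusted p = 0.638 with an estimated correlation), and -0.21 (adjusted p = 0.136) with the name series as a covariate and -0.23 (adjusted p = 0.218) among numbered libraries. Marrow stroma genes had a median of 0.31 (adjusted p = 0.0402; adjusted p = 0.558 with an estimated correlation).

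Stefin genes such as Cstdc5 and Stfa2 are expressed by neutrophils, so more neutrophils in the sorted cells could account for their rise. If the sort held more of the neutrophils already present in controls, stefin genes should rise about as much as other neutrophil genes. At 1 week after DSS the median log2 fold change was 3.35 for 6 stefin genes and 0.72 for 17 other neutrophil genes, a gap of 4.16 SD of the latter. After LPS it was 4.59 and 1.10, a gap of 6.01 SD. These gaps do not decide, since the stefin genes were chosen because they rose and several lie near the floor in controls (Cstdc5 at 0.26 CPM), so more neutrophils and a change in the state of neutrophils or macrophages cannot be told apart.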
